A study of Mus musculus with 42 samples.

How the data were processed

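PCIF1 is the cap-specific adenosine methyltransferase that makes m6Am, a methylated adenosine at the first transcribed position next to the mRNA cap. The mice carried a small Cas9-made deletion in Pcif1 that removes catalytic residues and brings in an early stop codon, per the labels' protocols. Founder embryos came from a hybrid of the C57BL/6J and DBA/2J strains, and founders were crossed to C57BL/6J. The labels list 42 samples in 14 groups of 3. Values for 24 libraries in 8 groups were analysed, and the 18 tissue RNA-seq libraries from brain, spleen and testes were not analysed here.

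A pair of assays supplied these 24 libraries. Ribosome footprinting of brain from wild-type (WT) and knockout (KO) mice gave 6 libraries of ribosome-protected fragments and 6 input RNA libraries from the same lysates. The m6Am-Exo-Seq assay of testes from heterozygous (HET) and KO mice gave 6 immunoprecipitated (IP) and 6 input libraries. It enriches capped RNA ends and then precipitates them with an antibody against m6A that also binds m6Am. The testes control was HET, not WT. The labels describe biological triplicates, and brains from 3 mice of each genotype for footprinting. They carry no replicate numbers, so libraries were numbered within a group in accession order and were not paired across groups. Limma p-values measure the spread between these samples, while permutation and Fisher p-values measure the spread across genes or random lists.

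The authors deposited 1 table per assay with 1 column per library, and each value is a signal, the reads of a gene divided by a factor for that library. The submitters' processing notes name Salmon 0.12.0, STAR, R 3.6.2, DESeq and DESeq2 1.25.10 without saying which made which table. The genome build, the annotation, the gene filters and the use of strand are not given in the sources used here. Both deposited tables also hold the authors' log2 fold and adjusted p-value for each gene, which per the values describe the difference between genotypes in footprint against input or in IP against input. The assumption fixed in advance was that the tables hold raw counts, which would have called for edgeR. They hold scaled values, so the stated fallback, limma on log2 values, became the main test.

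For testes, 100% of the values were whole multiples of the value of 1 read in their library, within a tolerance of 0.01. Whole reads could therefore be recovered, and edgeR (added after the data were seen) and DESeq2 (planned) were run on them as alternatives. For brain, 7.71 to 15.31% of the values were whole multiples, and the cause was not tested. No count model was run on the brain table. An exact 0 there may be a failed estimate, so a gene is described as listed at 0, with the value of each library.

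All fits used log2(signal + 1), and folds are on that scale, which understates the change of low genes. Genes with a signal of at least 10 in at least 3 libraries of a fit were tested. The test was limma 3.58.1 (empirical Bayes with a mean-variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Input RNA in KO against its control, and footprints in KO against WT, used their 6 libraries. Translational efficiency, the ratio of footprint to input, was tested as an interaction over all 12 brain libraries, and footprint against input within WT came from the same model. IP against input within HET, IP against input within KO and the difference between them came from 1 model over all 12 testes libraries. A gene was called PCIF1-dependent when it was enriched in the IP within HET (log2 above 0, adjusted p below 0.05) and the difference between genotypes was negative with adjusted p below 0.05.

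The median input fold of PCIF1-dependent genes was compared with that of the other tested genes, against 1000 random gene lists of the same size drawn within 20 expression bins. Because the HET and KO input libraries enter both the class and the fold, 100 sets of libraries were simulated without any change in input expression between genotypes but with the measured enrichment of each IP group, and the comparison was repeated with input libraries divided between both steps. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative and fry as another. Camera asks whether a list moved relative to the other genes, and fry whether it moved on balance in 1 direction.

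The designs, the alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. The lists held m6A, m6Am and cap machinery, translation factors, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, proteasome, spliceosome, replication-dependent histones, long non-coding RNAs, interferon-stimulated genes and the integrated stress response. Brain lists were markers of neurons, oligodendrocytes, astrocytes, microglia, endothelium, choroid plexus and blood cells, pituitary and hypothalamic hormones, and immediate early genes. Testis lists were markers of spermatogonia, meiotic spermatocytes, round and elongating spermatids, Sertoli cells, Leydig cells, testis macrophages, peritubular and vascular cells, and epididymis. Lists with fewer than 3 tested members were left out. These were the epididymis list (15 genes listed, 8 in the testes table, 1 tested in the inputs) and the blood cell list in testes (9 listed, 4 in the table, 0 tested).

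Named genes were Pcif1, the 10 highest and 10 lowest called folds per comparison, 2 predicted gene models per direction, up to 4 members of each list with the smallest p, and Mettl3, Mettl14, Fto, Alkbh5, Ythdf2 and Cmtr1. For the first group the libraries of both groups could not overlap (interactions excepted) and the mean had to reach 1 CPM, or 5 CPM in the enrichment comparisons. Not every gene so chosen is printed, and some are not reported here and were left out of counts of named genes. Identifiers were matched to symbols with a reference gene table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. It matched 50492 of 50765 identifiers in the brain table and 27368 of 27409 in the testes table.

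Alternatives were scaling by library size only, relative log expression size factors (RLE), pseudocounts of 0.1 and 10, no filter, a filter at a mean of 5 CPM, fits over other sets of libraries, and leaving out each library in turn. A fit on protein-coding genes of the brain table alone, scaled to their total, was added after the data were seen. Each test of single genes was run on simulated data with 200 changed genes. Limma recovered 80.6% of genes changed by 1 log2 unit in testes input RNA and 62.7% in brain footprints. Of the list tests only camera at the preset correlation was simulated, in testes inputs, where it called the 1 shifted list and 0 others. In brain input RNA limma recovered 2.99% at that size and 69.7% at 2 log2 units. Recovery at 1 log2 unit was 5.97% for the brain interaction and 7.46% for the testes interaction. The simulated spread was estimated on reads not corrected for depth, so it took in depth differences between replicates. Recovery may therefore be understated where depths were uneven, as in brain KO inputs and testes IP libraries. It does not settle which smaller changes could be detected in brain inputs. Differences in annotated start nucleotide were not tested, because no genome sequence was used here.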

Results

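Footprinting of brain and m6Am-Exo-Seq of testes each gave 12 libraries, 3 in each of 4 groups. Brain input libraries held between 15171398 and 17443872 estimated gene reads in WT and between 5528727 and 16205975 in KO, where replicate 2 was the shallow one. Footprint libraries held 13981589 to 16559721 in WT and 13613450 to 15497100 in KO. Ribosomal RNA genes took 72.7 to 75.8% of the WT footprint reads and 67.6 to 72.6% of the KO footprint reads, against 8.04 to 9.88% of brain inputs. Protein-coding genes took 22.4 to 30% of footprints and 41.1 to 43.9% of inputs. Testes inputs held 4224175 to 4907380 reads in HET and 4151226 to 4971554 in KO. IP libraries held 2689591 to 6574479 in HET and 1816831 to 4364847 in KO, with KO replicate 2 the shallowest. In testes the ribosomal RNA share differed with genotype, at 0.243 to 0.283% in HET inputs against 0.401 to 0.764% in KO inputs, and 0.0479 to 0.151% in HET IP against 0.409 to 0.421% in KO IP. No pair of replicates held identical values, and within every group replicates differed by more than counting noise (chi-square per gene 10.4 to 358 in brain and 2.92 to 27.7 in testes).

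Pcif1 (ENSMUSG00000039849) itself was measured first. In brain inputs its signal was 252.6, 318.3 and 387.7 in WT and 254.5, 200.7 and 259.4 in KO, a log2 fold of -0.41 ± 0.185 (SE, n = 3 per group) that did not pass limma's test (Benjamini-Hochberg adjusted p = 0.491). Its footprints gave 241.6, 229.2 and 233.5 in WT and 354.3, 301.7 and 182.2 in KO. In testes Pcif1 lay below the filter, with means of 7.76 ± 2.43 (SD, n = 3) in HET and 5.45 ± 3.36 in KO inputs, and 5.14 ± 3.34 in HET IP and 5.10 ± 4.61 in KO IP. The deletion removes a small part of the gene, so gene totals cannot show it and these values check no label.

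To find the transcripts that the antibody against m6A and m6Am enriches in testes, IP was compared with input in HET mice. The spermatid-associated genes Spata3 and Tex29 were enriched, from an input signal of 2655 ± 185 to 8004 ± 892 (SD, n = 3) in the IP for Spata3 and from 1341 ± 95.5 to 3578 ± 384 for Tex29. Their log2 folds were 1.59 ± 0.133 (SE) and 1.41 ± 0.148, with adjusted p of 7.11e-07 and 5.71e-06 by limma with Benjamini-Hochberg adjustment. Oaz3, the spermatid antizyme, rose from 9616 ± 729 to 22730 ± 8840, Catsper1, a sperm calcium channel subunit, from 524.6 ± 65.8 to 1177 ± 236, and Acr, the acrosomal protease, from 1900 ± 74.1 to 3319 ± 600. Fto, an RNA demethylase, was enriched from 423.4 ± 24.4 to 993.7 ± 55.8 (log2 1.23 ± 0.138, limma, Benjamini-Hochberg adjusted p = 1.06e-05). Depleted transcripts included the ribosomal protein genes Rpl9, from 3500 ± 361 to 412.9 ± 67.1 (log2 -3.09 ± 0.143), and Rps13, from 2484 ± 63.1 to 395.7 ± 180. Eef1a1, a translation elongation factor, fell from 4671 ± 309 to 804.3 ± 88.8, and Cox4i1, a cytochrome oxidase subunit, from 2587 ± 74.7 to 553.7 ± 165.

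Of 12387 genes tested with limma in the HET comparison, 1822 were enriched, 724 of them by over 1 log2 unit, and 1910 were depleted. With scaling by library size alone the split was 1453 and 2253. The round spermatid list had 7 of 14 members enriched and 0 depleted, and the elongating spermatid list 6 of 12 enriched and 1 depleted. Adjusted over the list alone these counts were 7 and 0, and 7 and 1. Their medians were 0.65 and 0.69, with camera adjusted p = 0.0114 and 0.00343, and both calls were lost at adjusted p = 0.286 with an estimated correlation. Among ribosomal proteins 59 of 75 were depleted and 1 enriched (62 and 2 adjusted over the list alone), with a median of -1.22 and camera adjusted p = 2.35e-29, against adjusted p = 0.0549 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 19 of 64 depleted and 3 enriched (21 and 3 adjusted over the list alone), with a median of -0.30 and camera adjusted p = 0.0042, lost at adjusted p = 0.286 with an estimated correlation. The other 15 lists tested had medians from -1.21 to 0.30 and passed no camera test, the smallest adjusted p being 0.182. In 6 of them the median, mean and test differed in sign. Mettl3, Mettl14, Alkbh5, Ythdf2 and Cmtr1 gave log2 values of -0.09, 0.27, -0.68, -0.03 and -0.33 and did not pass. Of the 78 named genes called here, 14 lost the call without at least 1 library.

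The same comparison in KO testes gives the enrichment present without PCIF1. Rbbp6, a ubiquitin ligase with a part in pre-mRNA processing, was enriched from 523.2 ± 50.8 to 3408 ± 794 (SD, n = 3), Sfswap, a splicing regulator, from 150.7 ± 13.0 to 1018 ± 196, and Fscb, a sperm fibrous sheath protein, from 61.7 ± 4.83 to 532.3 ± 142. Their log2 folds were 2.68 ± 0.206, 2.73 ± 0.233 and 3.05 ± 0.291 (SE), with limma's Benjamini-Hochberg adjusted p at most 9.09e-07. Fto was enriched here too, from 410.4 ± 17.8 to 1465 ± 261. Of the complex I subunit genes Ndufs4 and Ndufv2, both depleted, Ndufs4 went from 436.8 ± 8.2 to 54.7 ± 6.81 (log2 -2.98 ± 0.199, limma, Benjamini-Hochberg adjusted p = 3.53e-08) and Ndufv2 from 133.3 ± 15.2 to 10.1 ± 7.19. Rplp0, a ribosomal stalk protein, fell from 1632 ± 94.9 to 191.4 ± 39.3. Of the 12387 genes, 2632 were enriched and 3005 depleted in KO.

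Oxidative phosphorylation genes in KO had 42 of 64 members depleted and 2 enriched (44 and 3 adjusted over the list alone), with a median of -0.85, camera adjusted p = 8.3e-10 and adjusted p = 0.045 with an estimated correlation. Ribosomal proteins had 61 of 75 depleted and 3 enriched (64 and 3 adjusted over the list alone) and a median of -1.35. Their camera adjusted p = 4.92e-19 became adjusted p = 0.0903 with an estimated correlation. The other 17 lists, both spermatid lists among them, passed no camera test in KO and had medians from -0.90 to 0.71 with a smallest adjusted p of 0.142, with 55 members enriched and 67 depleted. Elongating spermatid markers had 5 of 12 enriched and 1 depleted, a median of 0.38 and fry adjusted p = 0.00922, and round spermatid markers 4 of 14 enriched and 4 depleted, a median of 0.11 and fry adjusted p = 0.988. Fry called 14 of the 19 lists in KO and 8 in HET. In 3 of the 17 the median, mean and test differed in sign. Across genes the HET and KO enrichments correlated at 0.61, with an SD across genes of 0.81 in HET and 1.01 in KO, and genes are not independent replicates. Enriched in both were 1153 genes (387 for independent lists), and depleted in both 1248 (463 for independent lists). Scaling by library size moved the median of all genes in the KO comparison to -0.17, from -0.07, and gave 2222 enriched and 3420 depleted. Of the 87 named genes called in KO, 9 lost the call without at least 1 library.

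**Figure D1:**
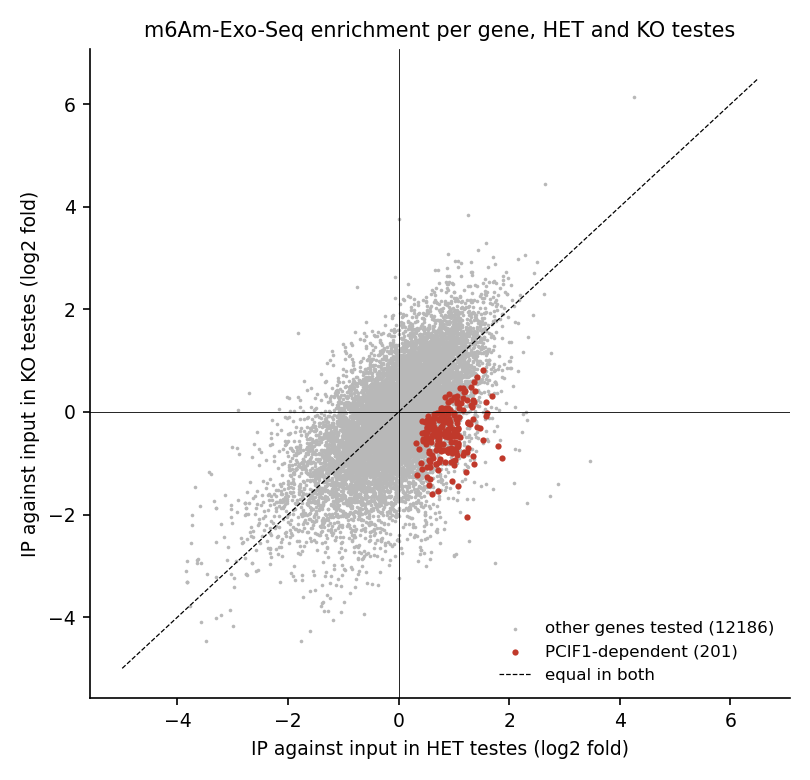
Each point is a gene, with its log2 ratio of IP to input signal in HET testes on the x axis and in KO testes on the y axis (means of 3 libraries per group). The 201 PCIF1-dependent genes are red and the other tested genes grey, with medians for the red genes of 0.89 in HET and -0.39 in KO.

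The difference between the KO and HET enrichments asks which IP signals depend on PCIF1. Cylc1, a protein of the sperm head cytoskeleton, fell relative to input, with an IP signal going from 75.0 ± 10.4 in HET to 11.3 ± 4.95 in KO (SD, n = 3), with inputs of 20.0 ± 5.36 and 20.6 ± 0.875. Its interaction was -2.77 ± 0.467 (log2, SE, limma, Benjamini-Hochberg adjusted p = 0.00253). The IP signal of Acr went from 3319 ± 600 to 1769 ± 196 (interaction -0.73 ± 0.193), and that of Psma4, a proteasome subunit, from 289.2 ± 18.9 to 107.6 ± 8.72 (-1.54 ± 0.214). Ldhc, the testis lactate dehydrogenase, went from 2212 ± 393 to 441.9 ± 56.2 in the IP (-1.90 ± 0.197, limma, Benjamini-Hochberg adjusted p = 8.87e-05) without being enriched in HET. Acrv1, an acrosomal vesicle protein, gave IP signals of 78.9 ± 13.4 and 6.90 ± 6.13, and Sf3b3, a splicing factor subunit, 52.1 ± 10.6 and 9.70 ± 3.62, each with a negative interaction that passed. Other genes rose relative to input. Vegfa, the angiogenic growth factor, went from 17.6 ± 9.39 to 88.4 ± 30.5 in the IP (2.30 ± 0.605), Inha, the inhibin subunit, from 18.9 ± 5.09 to 79.4 ± 14.6, and Ythdc1, a nuclear m6A reader, from 337.1 ± 93.8 to 655.2 ± 95.

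Over 12387 genes, limma called 774 with a lower and 461 with a higher IP-to-input ratio in KO than in HET, and 571 of the former were below -1. Of the 1822 genes enriched in HET, 201 were PCIF1-dependent (11.03%), among them Cylc1, Acr, Psma4 and Tex29. The remaining 573 genes with a lower ratio were not enriched in HET, among them Ldhc, Acrv1 and Sf3b3. The 201 genes had a median log2 enrichment of 0.89 in HET and -0.39 in KO, 163 lay at or below 0 in KO, and 11 were still enriched there. The class held 94, 109 or 114 genes tested in inputs without HET input replicate 1, 2 or 3, 113 or 132 without KO input replicate 2 or 3, and 1621 when it was taken from KO IP against HET IP alone. The 201 were selected on the same libraries, so these medians are not an independent estimate. The test of this interaction recovered 7.46% of simulated changes of 1 log2 unit. The simulated spread took in depth differences between libraries, so this share may be too low. Failing the test does not show independence of PCIF1, so enriched genes outside the class may depend on PCIF1 too. Oxidative phosphorylation genes had 17 of 64 members lower and 1 higher (24 and 2 adjusted over the list alone), with a median of -0.60 and camera adjusted p = 4.89e-07, against adjusted p = 0.106 with an estimated correlation. Members included Ndufs4, from 219.2 ± 64.9 to 54.7 ± 6.81 in the IP, Uqcrq of complex III, from 326.3 ± 66.0 to 88.0 ± 22.0, and Cox5b of complex IV, from 6837 ± 171 to 3396 ± 103. Round spermatid markers had 5 of 14 lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.57 and camera adjusted p = 0.0192, lost at adjusted p = 0.289 with an estimated correlation. Examples were Spaca1 and Zpbp, both sperm-egg interaction proteins, with IP signals of 273.9 ± 87.6 against 78.8 ± 16.8 and 250.0 ± 130 against 39.7 ± 14.6. The other 17 lists had medians from -0.82 to 0.92, a smallest adjusted p of 0.103 and 4 with signs that differed between median, mean and test, and fry called 5 of the 19 lists. Fto, Mettl3, Mettl14, Alkbh5, Ythdf2 and Cmtr1 gave 0.59, 0.01, -0.76, 0.94, 0.24 and 0.66 and did not pass. The number called was 605, 662 or 640 without HET input replicate 1, 2 or 3, 814, 546 or 675 without KO input replicate 1, 2 or 3, 793 with no filter and 2988 when KO IP was compared with HET IP alone. Of the 56 named genes called here, 27 lost the call without at least 1 library.

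**Figure D2:**
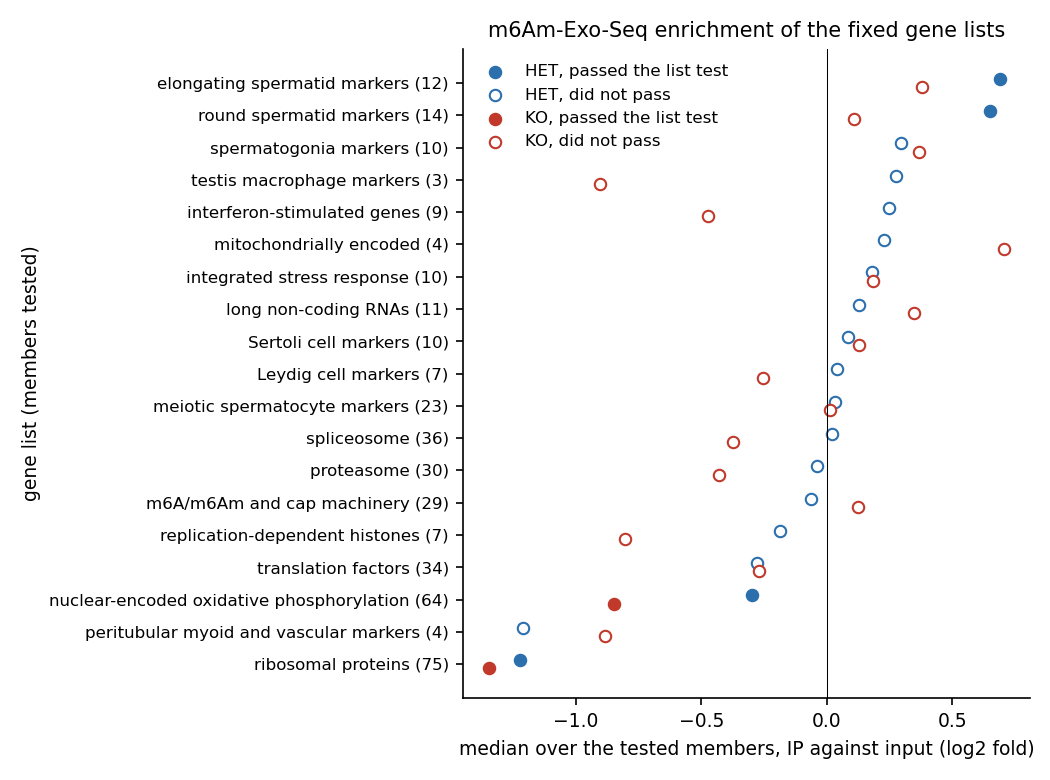
Each row is a gene list and each symbol its median log2 ratio of IP to input signal, in HET and in KO testes. Filled symbols passed the camera test at an adjusted p of 0.05, with ribosomal proteins at -1.22 in HET and -1.35 in KO.

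Expression in testes was compared between KO and HET inputs to ask which transcripts change without PCIF1. Genes that fell included Rsph3b, a radial spoke protein of the flagellum, from 370.9 ± 89.4 to 93.6 ± 3.84 (SD, n = 3), Uqcc2, a complex III assembly factor, from 205.3 ± 47.1 to 52.1 ± 3.78, and Tfb1m, a mitochondrial rRNA methyltransferase, from 106.1 ± 13.5 to 33.1 ± 11.2. Fbxw5, a ubiquitin ligase adaptor, fell from 7288 ± 580 to 2434 ± 939, Paxx, a DNA end-joining factor, from 441.4 ± 57.5 to 164.9 ± 31.2, and Ccnb1ip1, a meiotic crossover factor, from 117.0 ± 12.3 to 44.0 ± 17.4. Their log2 folds ran from -1.95 ± 0.156 (SE) for Rsph3b to -1.43 ± 0.142 for Paxx, and limma's Benjamini-Hochberg adjusted p was at most 0.00412. Sfi1, a centrosomal protein, rose from 108.5 ± 29.8 to 619.3 ± 239 (log2 2.45 ± 0.255, limma, Benjamini-Hochberg adjusted p = 0.000152), and Tap1, a peptide transporter of antigen presentation, from 6.74 ± 1.43 to 19.5 ± 2.05. Mettl3, the catalytic subunit of the m6A methyltransferase, rose from 82.1 ± 2.95 to 179.3 ± 28.1 (1.11 ± 0.139), and Dxo, a decapping exonuclease, from 563.3 ± 80.3 to 882.1 ± 94.9. The folds of these named genes could reflect strain alleles as well as loss of PCIF1, and the 2 were not told apart. Predicted models were called too, with 1700030C10Rik at 185.3 ± 19.8 in HET and 1.93 ± 0.633 in KO.

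Of 11278 genes tested with limma in testes inputs, 374 rose and 678 fell, 57 and 75 of them by over 1 log2 unit. With scaling by library size alone the split was 581 higher and 463 lower. Round spermatid markers had 6 of 14 members lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -0.42 and camera adjusted p = 3.25e-07. Elongating spermatid markers had 2 of 11 lower and 0 higher (8 and 0 adjusted over the list alone), with a median of -0.28 and camera adjusted p = 0.000557. Both calls were lost at adjusted p = 0.408 with an estimated correlation. Catsper4 fell from 534.2 ± 23.1 to 287.1 ± 34.8 (log2 -0.90 ± 0.103), Zpbp from 198.5 ± 13.1 to 112.9 ± 11.3, Crem, a spermatid transcription factor, from 1527 ± 102 to 1172 ± 90.6, and Oaz3 from 9616 ± 729 to 7887 ± 21.1. Spermatogonia markers had 0 of 9 members called over all genes (limma, 2 with an unadjusted p below 0.05) and 2 higher adjusted over the list alone, with a median of 0.34. Their camera adjusted p = 0.0418 was lost at adjusted p = 0.408 with an estimated correlation, and fry called 3 lists in this comparison, both spermatid lists and spermatogonia. Among spermatogonia markers, Etv5, a spermatogonial stem cell factor, had signals of 49.7 ± 5.58 and 72.2 ± 0.384. Mitochondrially encoded genes had 2 of 4 higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.65 and camera adjusted p = 0.025, lost at adjusted p = 0.48 with an estimated correlation. The members called were mt-Atp6, from 222.5 ± 30.9 to 345.9 ± 38.3, and mt-Nd4, from 80.0 ± 24.8 to 123.5 ± 6.32.

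The other 15 lists in testes inputs passed no camera test, with a smallest adjusted p of 0.138. Their medians were 0.17 for meiotic spermatocytes, -0.03 for Sertoli cells, 0.16 for Leydig cells, -0.06 for macrophages and 0.20 for peritubular and vascular cells. They were 0.04 for m6A, m6Am and cap machinery, 0.22 for interferon-stimulated genes, 0.31 for the integrated stress response, -0.01 for translation factors and -0.00 for ribosomal proteins. Oxidative phosphorylation stood at -0.02, long non-coding RNAs at -0.49, proteasome at 0.12, spliceosome at 0.07 and histones at -0.35. The oxidative phosphorylation and Sertoli medians differed in sign from the mean and test, and the medians of translation factors, ribosomal proteins, oxidative phosphorylation, Sertoli cells and macrophages turned positive under another scaling. Single members were called in these lists, 12 higher and 16 lower. Meiob, a meiotic recombination factor, rose from 68.2 ± 17.8 to 131.7 ± 5.88, while the cohesin Rec8 fell from 143.5 ± 15.1 to 87.7 ± 5.92 and Ldhc from 2637 ± 60.6 to 1986 ± 98.9. Hist1h2ba, the testis variant of histone H2B, fell from 224.5 ± 11.2 to 112.0 ± 44.0, and Ddit3, a stress transcription factor, from 452.3 ± 56.8 to 307.2 ± 31.9. Mettl14, Fto, Alkbh5, Ythdf2 and Cmtr1 gave 0.06, -0.04, 0.68, 0.26 and -0.09 and did not pass. The number called was 615, 508 or 281 without HET replicate 1, 2 or 3, 438 or 459 without KO replicate 2 or 3, and 24 when the spread was estimated over all 12 testes libraries. Of the 57 named genes called here, 26 lost the call without at least 1 library.

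Whether transcripts whose IP signal falls relative to input without PCIF1 change in level was asked by comparing the input folds of the PCIF1-dependent genes with those of other genes. The 201 genes had a median log2 fold of -0.23 in KO against HET input, and the other 11077 genes a median of 0.00. The difference of -0.226 was farther from the centre than that of any of 1000 random lists matched on expression, 95% of which lay between -0.074 and 0.019 (permutation p = 0.001, two-sided, the smallest they can give). Of the 201 genes 44 were called lower in KO input and 5 higher. In the same inputs round and elongating spermatid markers had medians of -0.42 and -0.28. The class and the fold share input libraries, and simulated libraries without any change in expression gave a difference of 0.205 (0.145 to 0.251 in 100 draws), of opposite sign, with a class of 339 genes at the median. The simulation used a dispersion of 0.0404 for all libraries, estimated on reads not corrected for depth, so it took in depth differences. For inputs alone the dispersion stood at 0.01, the lower bound set for it. The simulation may therefore overstate the size of this shift. With input libraries divided between both steps, each fold came from 1 HET and 1 KO library, and the difference ran from -0.172 to -0.352 over 9 divisions, with classes of 40 to 70 genes and permutation p over genes from 0.001 to 0.022. All IP libraries stayed in the class, and the labels do not say which IP and input libraries share an animal, so these divisions are not independent tests. For the 500 genes with the most negative interactions, enriched in HET or not, it was -0.016 over the 414 that could be tested (permutation p = 0.157).

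**Figure D3:**
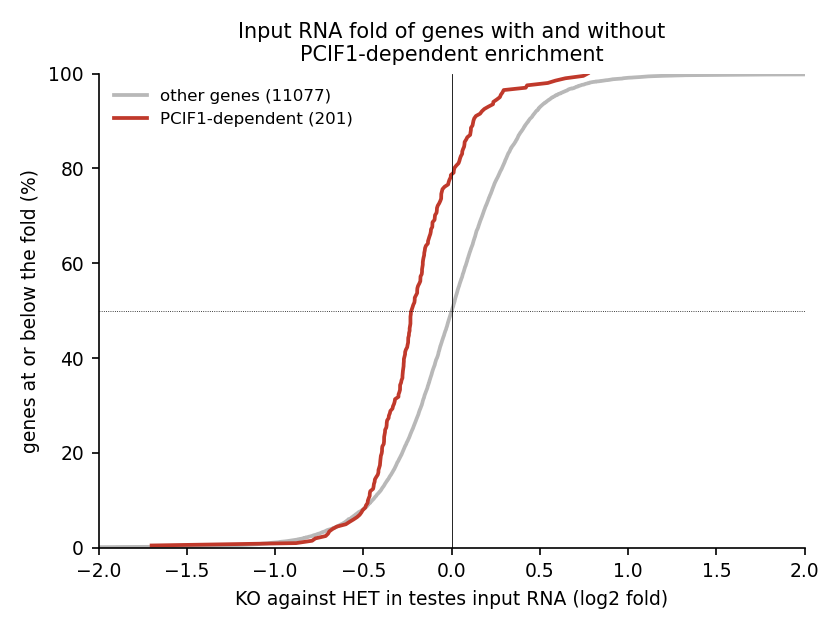
The curves give the cumulative percent of genes by log2 fold of input signal in KO against HET testes, for 201 PCIF1-dependent genes and 11077 other genes. The curve of PCIF1-dependent genes lies to the left, with a difference of medians of -0.226, and values beyond the axis are not shown.

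In brain, input RNA of KO and WT mice was compared to ask for expression changes in a second tissue. Aldh1l2, a mitochondrial folate enzyme, rose from 17.5 ± 0.742 in WT to 71.9 ± 10.5 in KO (SD, n = 3), Noct, the circadian phosphatase nocturnin, from 692.6 ± 71.1 to 1406 ± 115, and Sptb, a spectrin, from 461.5 ± 38.4 to 785.2 ± 13.6. Rara, a retinoic acid receptor, fell from 95.2 ± 15.3 to 14.5 ± 2.61, Focad, focadhesin, from 682.6 ± 53.9 to 303.6 ± 48.2, and Fam234b from 1085 ± 59.3 to 503.3 ± 79.8. Log2 folds were 1.97 ± 0.21 (SE) for Aldh1l2 and -2.63 ± 0.236 for Rara, with limma's Benjamini-Hochberg adjusted p of 0.0244 and 0.0106. Atp6v0c, Gapdh and Rps18 gave folds of -0.99, -0.83 and -1.40, but these genes have near-identical copies and their values are uncertain. The enolase copy Eno1b was listed at 0 in all 3 WT libraries and at 912.8, 1323 and 1585 in KO, and shares sequence with Eno1.

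Of 15298 genes tested with limma in brain inputs, 27 rose and 12 fell, and 14 of these 39 were protein-coding and 13 pseudogenes. Without KO replicate 1 or 2 the balance turned, to 4 higher and 17 lower or to 3 higher and 7 lower. Also higher were CT010467.1, an 18S ribosomal RNA model, from 104.1 ± 29.7 to 1935 ± 1290, and AY036118, counted here with ribosomal RNA, from 31.25 ± 27.2 to 1912 ± 444 (limma, Benjamini-Hochberg adjusted p = 0.0248 and 0.0101). In footprints AY036118 stood the other way, at 6043000 and 2814000 in WT replicates 1 and 3 and listed at 0 in WT replicate 2 and all 3 KO libraries. Oligodendrocyte markers had 1 of 15 members higher and 0 lower over all genes (9 and 0 adjusted over the list alone), with a median of 0.40 and camera adjusted p = 6.23e-07, against adjusted p = 0.082 with an estimated correlation. The myelin genes Mbp and Ugt8a, which did not pass over all genes, had signals of 6040 ± 541 and 8689 ± 46.5, and of 489.8 ± 32 and 818.6 ± 105. Microglia markers had 0 of 12 members called over all genes (limma, 5 with an unadjusted p below 0.05) and 4 lower adjusted over the list alone. Their median was -0.37 with camera adjusted p = 1.92e-05, lost at adjusted p = 0.41 with an estimated correlation. Fry called 3 lists, which were oligodendrocyte and microglia markers and proteasome (adjusted p = 0.000947, 0.0498 and 0.000947). The complement genes C1qb and C1qc had signals of 105.9 ± 21.5 in WT and 37.2 ± 16.0 in KO, and of 141.2 ± 32.3 and 55.5 ± 17.4. Ribosomal proteins had 1 of 79 lower and 0 higher, also adjusted over the list alone, with a median of -0.07 and camera adjusted p = 0.0112, lost at adjusted p = 0.528 with an estimated correlation. The 1 member called was Rps18.

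The other 17 lists in brain inputs, proteasome among them, had 0 members called with limma over all genes (48 with an unadjusted p below 0.05) and a smallest camera adjusted p of 0.207. Adjusted over the list alone, long non-coding RNAs had 3 members higher and 1 lower. Blood cells, hormones and translation factors had 1 lower each on that basis. Median log2 folds were -0.01 for neurons, 0.02 for astrocytes, 0.17 for endothelium, -0.08 for choroid plexus, -0.00 for blood cells, 0.03 for hormones and 0.09 for immediate early genes. They were 0.05 for m6A, m6Am and cap machinery, 0.03 for interferon-stimulated genes, -0.03 for the integrated stress response, 0.03 for translation factors, 0.06 for oxidative phosphorylation and 0.07 for mitochondrially encoded genes. Long non-coding RNAs stood at -0.02, proteasome at 0.10, spliceosome at 0.03 and histones at 0.07. Median, mean and test differed in sign for neurons, hormones, immediate early genes, interferon-stimulated genes, the integrated stress response, translation factors, long non-coding RNAs, spliceosome and histones. Under another scaling the medians of astrocytes, blood cells, hormones, interferon-stimulated genes, translation factors and spliceosome changed sign. Mettl3, Mettl14, Fto, Alkbh5, Ythdf2 and Cmtr1 gave 0.05, 0.12, 0.18, 0.02, 0.12 and -0.26 and did not pass. The number called was 21, 10 or 7 without KO replicate 1, 2 or 3, 17, 14 or 24 without WT replicate 1, 2 or 3, 22 at a mean of 5 CPM, and 13 (6 higher and 7 lower) for protein-coding genes alone, scaled to their total. Of the 21 named genes called here, 16 lost the call without at least 1 library.

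**Figure D4:**
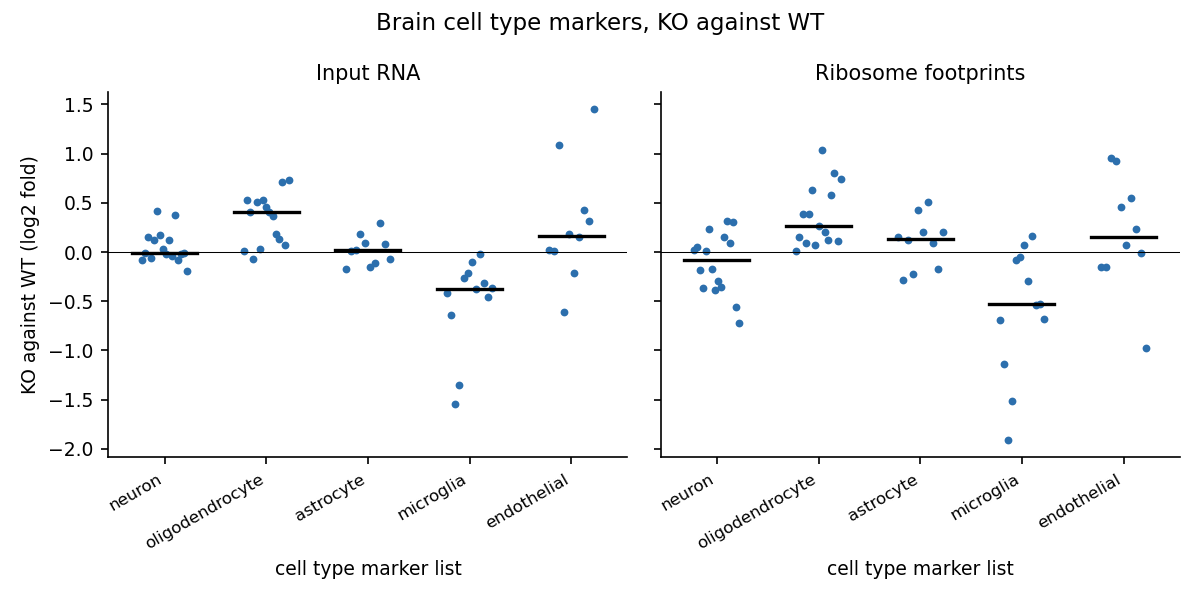
Points are log2 folds of single marker genes in KO against WT brain, for input RNA and for footprints, and bars are list medians. Oligodendrocyte medians stand at 0.40 and 0.26 and microglia medians at -0.37 and -0.53.

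Ribosome footprints in KO and WT brain were compared to look for effects on the RNA being translated. Abcb1a, the drug efflux pump of brain capillaries, rose from 18.5 ± 1.86 to 480.3 ± 212 (SD, n = 3), Hmgcs1, an enzyme of cholesterol synthesis, from 1854 ± 182 to 3965 ± 327, and Chst15, a chondroitin sulfotransferase, from 69.4 ± 14.1 to 231.5 ± 24.2. Mlycd, malonyl-CoA decarboxylase, fell from 136.5 ± 1.73 to 19.3 ± 7.3, Bbs7, a protein of primary cilia, from 120.1 ± 10.0 to 27.1 ± 3.81, Vps52, a vesicle tethering factor, from 1349 ± 326 to 331.1 ± 44.4, and Rnps1, an exon junction factor, from 767.1 ± 61.6 to 334.9 ± 33.6. Log2 folds were 4.54 ± 0.329 (SE) for Abcb1a, 1.10 ± 0.132 for Hmgcs1 and -2.82 ± 0.311 for Mlycd, with limma's Benjamini-Hochberg adjusted p of 0.00274, 0.0341 and 0.0245. Eno1b was listed at 0 in all WT footprint libraries too and at 41.91, 168.7 and 160.2 in KO. Atp6v0c, at -2.23, is uncertain because of near-identical copies.

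Among 14377 genes tested with limma, 21 were higher and 11 lower in KO footprints, and 14 of these 32 were protein-coding and 10 pseudogenes. With scaling by library size alone 19 were higher and 6 lower, and the median of all genes moved from 0.01 to 0.26. Oligodendrocyte markers had 0 of 15 members called over all genes (limma, 6 with an unadjusted p below 0.05) and 4 higher adjusted over the list alone, with a median of 0.26. Their camera adjusted p = 9.56e-05 was lost at adjusted p = 0.606 with an estimated correlation. Mag, a myelin adhesion protein, had signals of 2708 ± 214 and 4203 ± 378. Microglia markers had 0 of 12 called (limma, 3 with an unadjusted p below 0.05) and 3 lower adjusted over the list alone, with a median of -0.53 and camera adjusted p = 0.00409, lost at adjusted p = 0.606 with an estimated correlation. Mitochondrially encoded genes had 0 of 13 called over all genes or adjusted over the list alone (limma, 1 with an unadjusted p below 0.05), a median of -0.36 and camera adjusted p = 0.03, lost at adjusted p = 0.722 with an estimated correlation. Fry called 0 lists. The other 17 lists had medians from -0.50 for interferon-stimulated genes to 0.48 for long non-coding RNAs, 0 members called by limma over all genes (70 with an unadjusted p below 0.05) and a smallest camera adjusted p of 0.135. In 5 of them median, mean and test differed in sign. Adjusted over the list alone, immediate early genes had 1 member higher and 2 lower, blood cells 2 lower and histones 1 lower. Mettl14, the partner of METTL3, had signals of 188.2 ± 28.3 and 81.6 ± 19.4, a log2 fold of -1.21 that did not pass, and Pcif1, Mettl3, Fto, Alkbh5, Ythdf2 and Cmtr1 gave 0.20, -0.41, -0.46, 0.22, -0.10 and 0.34. Of the 16 named genes called here, 13 lost the call without at least 1 library.

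The footprint count rested on single libraries. Leaving out WT replicate 2 raised it to 956 genes (468 higher and 488 lower). Leaving out WT replicate 1 gave 17 genes (17 higher and 0 lower), and leaving out WT replicate 3 gave 18 (17 higher and 1 lower). Without KO replicate 1, 2 or 3 limma called 0 genes, with 1090, 1049 and 857 at an unadjusted p below 0.05. Across genes, WT footprint replicate 2 correlated at 0.921 to 0.926 with the KO footprint libraries and at 0.903 and 0.911 with WT replicates 1 and 3, which correlated at 0.938 with each other. The count was 143 with the spread estimated over all 12 brain libraries, 14 with a pseudocount of 0.1, 7 at a mean of 5 CPM and 7 for protein-coding genes alone, scaled to their total.

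**Figure D5:**
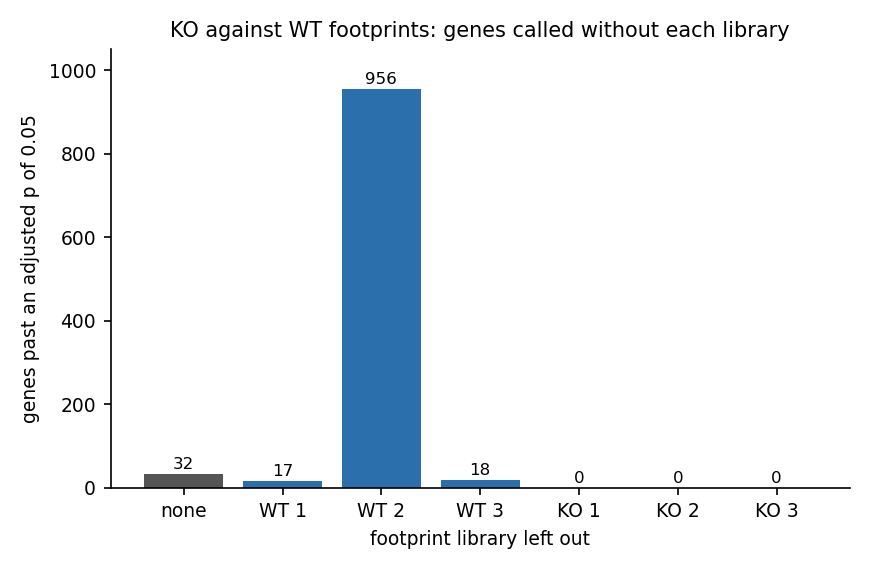
Bars give the number of genes limma called between KO and WT footprints with all 6 libraries (32) and with each library left out. Without WT replicate 2 the number was 956, and without any of the KO replicates 0.

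Translational efficiency was then compared between genotypes. Abcb1a footprints rose relative to input, which was 394.4 ± 122 in WT and 606.2 ± 254 in KO (SD, n = 3), with an interaction of 3.96 ± 0.526 (log2, SE, limma, Benjamini-Hochberg adjusted p = 0.0133). Erc1, a scaffold of the presynaptic active zone, went from 438.4 ± 16.9 to 360.8 ± 13.5 in input and from 342.0 ± 24.5 to 551.6 ± 39.5 in footprints (0.97 ± 0.149). Rara rose in efficiency (2.10 ± 0.337), its footprints being 30.4 ± 0.859 and 20.8 ± 2.39 while its input fell. Lower efficiency was measured for H6pd, a sugar phosphate dehydrogenase of the endoplasmic reticulum, whose footprints went from 94.3 ± 22.0 to 20.3 ± 5.9 at inputs of 126.1 ± 22.3 and 137.2 ± 14.9 (-2.31 ± 0.364). The efficiency of Mlycd fell by 2.14 ± 0.315 on the log2 scale, and that of Cotl1, an actin-binding protein, fell by 1.13 ± 0.175. The pseudogene Rps13-ps1, whose value is uncertain because it resembles Rps13, was listed at 0 in all WT footprint libraries and at 66.46, 66.54 and 83.22 in KO, and the small nucleolar RNA Snord116l9 at 525.1, 77.17 and 1625 in WT and at 0 in all KO footprint libraries.

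Limma called 15 genes with higher and 16 with lower translational efficiency among 16527, of which 11 were protein-coding. None of the 20 lists passed camera or fry, with medians from -0.48 to 0.27, a smallest camera adjusted p of 0.331 and signs that differed in 3. Within the lists limma called 0 members over all genes (62 with an unadjusted p below 0.05). Pcif1, Mettl3, Mettl14, Fto, Alkbh5, Ythdf2 and Cmtr1 gave 0.61, -0.46, -1.33, -0.64, 0.20, -0.22 and 0.60 and did not pass. Scaling by library size alone moved the median of all genes to 0.22. The count was 874 without WT footprint replicate 2, 18 without WT footprint replicate 3, 20 without WT input replicate 1 or 2, and 15 without KO input replicate 3. It was 11 at a mean of 5 CPM, 50 with a pseudocount of 0.1 and 4 (3 higher and 1 lower) for protein-coding genes alone, scaled to their total. Of the 15 named genes called here, 10 lost the call without at least 1 library.

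Within WT brain, footprints were set against input to describe which RNAs stood high or low in footprints relative to input. Camk2a, a synaptic kinase, rose from an input signal of 1621 ± 68.7 to 15480 ± 970 in footprints (SD, n = 3), Slc1a2, the astrocyte glutamate transporter, from 6802 ± 644 to 28490 ± 2460, Sox10, an oligodendrocyte transcription factor, from 53.2 ± 12.5 to 546.9 ± 28.4, and Egr1, an immediate early factor, from 167.4 ± 33.5 to 1776 ± 409. The non-coding Malat1 went from 43150 ± 4260 to 708.0 ± 202, Gas5 from 750.1 ± 64.8 to 50.7 ± 5.78, the spliceosomal RNA gene Rnu5g from 41930 ± 3440 to 25.5 ± 36.8, and the mitochondrial tRNA gene mt-Tl2 from 685000 ± 127000 to 437.1 ± 37.4. Log2 folds were 3.25 ± 0.0889 (SE) for Camk2a and -5.97 ± 0.39 for Malat1, with limma's Benjamini-Hochberg adjusted p of 4.46e-10 and 2.94e-07. Of the methylation genes, Fto (1.69), Mettl14 (2.15) and Ythdf2 (0.65, but -0.42 with scaling by library size alone) rose, Alkbh5 fell (-1.30), and Pcif1, Mettl3 and Cmtr1 gave -0.42, -0.37 and -0.21 and did not pass. Antisense transcripts such as Nespas, at 5.99, are uncertain because the use of strand in counting is not given in the sources used here.

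Limma called 4168 genes with more and 4809 with less footprint than input signal in WT brain among 16527. The level depends on the scaling, since library size alone moved the median of all genes from -0.09 to -1.14 and gave 1282 higher and 10046 lower, and protein-coding genes alone, scaled to their total, had a median of -0.28. Neuron markers had 13 of 16 members higher and 1 lower (14 and 1 adjusted over the list alone), oligodendrocyte markers 13 of 15 and 0 (13 and 0 adjusted over the list alone), astrocyte markers 9 of 10 and 1 (9 and 1), proteasome 25 of 31 and 0 (26 and 0), oxidative phosphorylation 42 of 74 and 9 (44 and 9) and spliceosome 19 of 41 and 3 (19 and 3). Their medians were 0.97, 0.86, 1.43, 0.70, 0.62 and 0.57, camera adjusted p ran from 3.17e-07 for proteasome to 0.0059 for spliceosome, and all 6 held, with adjusted p from 0.00461 to 0.0414 with an estimated correlation. Ribosomal proteins had 50 of 79 lower and 3 higher (51 and 3 adjusted over the list alone), with a median of -1.11, and long non-coding RNAs 16 of 19 lower and 0 higher (16 and 0), with a median of -3.21. Both held as well, at adjusted p = 0.0115 and 0.00849 with an estimated correlation. Microglia markers (median 0.70), hormones (1.67), immediate early genes (1.15) and histones (0.66) passed camera with adjusted p of 0.0237, 0.00363, 0.000466 and 0.0172. These were lost, at adjusted p of 0.205, 0.144, 0.205 and 0.281 with an estimated correlation. Adjusted over the list alone, they had 5, 7, 10 and 15 members higher and 0, 0, 1 and 3 lower. With scaling by library size alone, which lowered all genes alike, the medians of neuron, oligodendrocyte, microglia, oxidative phosphorylation, proteasome, spliceosome and histone lists turned negative, but relative to all genes they stayed at 1.04, 0.92, 0.77, 0.69, 0.76, 0.65 and 0.73. The other 8 lists had medians from -0.05 to 0.88, a smallest camera adjusted p of 0.148, 42 members higher and 27 lower, and signs that differed in 2. Of the 101 named genes called here, 7 lost the call without at least 1 library.

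Genes PCIF1-dependent in testes were then followed in brain inputs, which share no library with the definition of the class. The 93 genes that could be tested had a median log2 fold of -0.08 in KO against WT, and the other 8869 genes a median of 0.02, a difference of -0.0943 (permutation p = 0.007, two-sided, 1000 matched lists). None of the 93 was called singly by limma in brain. The difference did not pass at -0.0576 without KO brain input replicate 2 (p = 0.073), at -0.0852 without replicate 3 (p = 0.058) or at -0.0671 without WT replicate 2 (p = 0.099), all by permutation. With the class defined without 1 testes library it did not pass without IP HET replicate 1 or 2 (-0.0494 and -0.0500, permutation p = 0.117 and 0.067), IP KO replicate 2 or 3 (-0.0496 and -0.0486, permutation p = 0.182 and 0.215), or the inputs HET 1, HET 2, HET 3 or KO 1 (-0.109, -0.0944, -0.0941 and -0.0823, permutation p from 0.05 to 0.058). For the 500 most negative interactions it was -0.0351 (permutation p = 0.229).

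The authors' deposited table for brain gives an adjusted p below 0.05 for 126 of 16307 genes, 58 with a positive and 68 with a negative log2 fold. Its folds correlated at 0.778 across genes with the interaction computed here, with a median absolute difference of 0.0462, and 18 of the 31 genes called here are among the 126. Abcb1a stands at 4.07, H6pd at -2.36 and Mlycd at -2.11 in it. The authors' deposited table for testes gives 1754 of 10929 genes, 716 positive and 1038 negative, with a correlation of 0.964, a median absolute difference of 0.0433 and 1206 of the 1235 genes called here.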

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

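The edgeR tests on recovered testes reads were chosen after the data were seen, although edgeR on raw counts had been planned as the main test. The tests on protein-coding brain genes alone, scaled to their total, were also chosen then. The same holds for the tests of PCIF1-dependent genes limited to genes also tested in brain or without spermatid markers. All other settings were planned. The test of start nucleotides was not run, for want of a genome sequence, nor was DESeq2 on the brain values, most of which were not whole reads. No paired analysis was possible because the labels carry no replicate numbers. Except where fewer genes or libraries entered a fit, the cause was not tested, and it was not tested for protein-coding genes either, where gene set and scaling changed together.

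Counts of called genes within 1.5 times the reported one in all settings were those of enrichment within HET (2671 to 4175 with 1 library left out, 4112 by edgeR, 3981 by DESeq2), of enrichment within KO (4444 to 5934, 5557 and 5358) and of footprint against input within WT (7803 to 9281). Brain input RNA gave 39 genes, 22 at a mean of 5 CPM, 13 among protein-coding genes and 7 to 24 with 1 library left out. Footprints gave 32 genes, 143 in a fit over all 12 libraries, 7 at a mean of 5 CPM, 7 among protein-coding genes, 14 with a pseudocount of 0.1 and 0 to 956 with 1 library left out. With limma the 0 held without any 1 of the KO libraries, where 1090, 1049 and 857 genes had an unadjusted p below 0.05. Translational efficiency between genotypes gave 31 genes, 11 at a mean of 5 CPM, 4 among protein-coding genes, 50 with a pseudocount of 0.1 and 15 to 874 with 1 library left out. Testes input RNA gave 1052 genes, 24 in a fit over all 12 libraries, 1071 by edgeR, 900 by DESeq2 and 281 to 1433 with 1 library left out. The loss of enrichment gave 1235 genes, 2988 from IP libraries alone, 571 below -1, 793 without a filter, 1418 by edgeR, 1766 by DESeq2 and 546 to 1729 with 1 library left out. Of 30 lists called by camera in all comparisons, the setting with an estimated correlation left 9, and fry called 50. Calls were lost with that setting even at estimates below the preset 0.01. Such estimates were -0.0114 for oligodendrocyte markers in brain inputs and -0.107 for spermatogonia markers in testes inputs. Correlation between genes alone therefore does not account for the losses.

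The expression difference of PCIF1-dependent genes in testes was -0.150 to -0.249 with 1 library left out and -0.165 for genes also tested in brain, and passed in each of these. For the 500 most negative interactions it was -0.016 and did not pass (permutation p = 0.157). The class from IP libraries alone gave -0.294, but it takes in genes whose RNA fell, so its sign is built in. Removing spermatid markers left 199 of the 201 genes, too small a change to test the part of spermatids in this difference. In brain the difference was -0.0351 for the 500 most negative interactions (permutation p = 0.229) and -0.0486 to -0.1297 with 1 library left out, with permutation p from 0.002 to 0.215.

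Named genes reversed only in footprint against input within WT with scaling by library size alone, where the median of all genes was -1.14. These were Asns (-0.086), Cldn5 (-0.091), Csf1r (-0.47), Eif3a (-0.16), Hist1h4d (-0.18), Itm2a (-0.68), Olig1 (-0.33), Sf3b2 (-0.11) and Ythdf2 (-0.42). Other settings kept direction and call in 138 of 153 values for brain input RNA, 84 of 118 for footprints, 74 of 93 for translational efficiency, 435 of 491 for testes inputs and 476 of 502 for the loss of enrichment. With 1 library left out these were 39 of 105, 20 of 75, 88 of 171, 232 of 309 and 507 of 672. In brain inputs, where KO replicate 2 had 5528727 estimated reads, simulated changes of 1 log2 unit were recovered in 2.99% of genes at a dispersion of 0.113. In testes inputs it was 80.6% at 0.01, the lower bound set for the dispersion, and in footprints 62.7% at 0.0279. These dispersions came from reads not corrected for depth, so depth and dispersion were not told apart. They do not compare the spread between replicates of the assays.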

Other observations

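The tests of pseudogenes, of called neighbours, of testis cell types and of WT footprint replicate 2 were chosen after the results were seen, and those of the genes around Pcif1 and of other splits before. Values of 3 single genes follow. In KO testes Smad3, a transducer of TGF-beta signals, rose from an input of 7.64 ± 1.97 to 83.0 ± 14.5 in the IP (SD, n = 3). Gapdhs, the sperm glycolytic dehydrogenase, had IP signals of 7456 ± 3060 in HET and 2309 ± 186 in KO, with an interaction of -1.38 (limma, Benjamini-Hochberg adjusted p = 0.0063). The nuclear non-coding Malat1 was enriched in the HET IP, from 423.9 ± 72 to 1044 ± 167.

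Genes called in brain inputs were compared with those called elsewhere. Among 13386 genes tested in both, 6 were higher in KO in input and in footprints (Eno1b, Gm25813, Gm10260, Gm13394, Gm9825 and Gm5855, named after their values were seen) and 1 was lower in both (Atp6v0c). Input and footprints came from the same lysates, so no overlap for independent lists is given, and Eno1b and Atp6v0c have near-identical copies. Among 8429 genes tested in brain and testes inputs, 1 was higher in both and 1 lower in both, against 0.226 and 0.191 for independent lists.

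The genes called in brain input RNA held 13 pseudogenes among 39, against 628 among the 15298 tested. None of the 28 called genes with a known position lay within 200 annotated genes of Pcif1 (0%, exact 95% interval 0 to 12.3%). For these 28, that argues against linked DBA/2J passenger alleles in this window as the main cause. Only 124 of 14184 tested genes lay there, so the odds ratio of 0 (exact interval 0 to 16.2) cannot exclude enrichment. Strain alleles outside the window stay open. Pseudogenes were over-represented with an odds ratio of 11.9 (5.59 to 24.2, Fisher's exact test, two-sided p = 2.52e-09), so reads shared between near-identical copies may account for part of the calls. The odds ratio was 7.71 in footprints and 6.17 for translational efficiency. Loss of PCIF1, the difference the design names, stays open for the protein-coding genes and was not tested apart from these.

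The changes in testes input RNA might reflect strain background or tissue makeup as well as genotype. DBA/2J alleles within 200 annotated genes of Pcif1 are argued against as the main cause. Of the 976 called genes with a position, 6 lay there (odds ratio 0.659, 0.235 to 1.5, Fisher's exact test, two-sided p = 0.474). Blocks of strain alleles elsewhere stay open, since 21.1% of called genes had a called neighbour against a random median of 15.9% (permutation p = 0.00088), and without predicted gene models 18.9% against 15% (permutation p = 0.0149). By chromosome, predicted models included, 15.5% of tested genes were called on chromosome 14 and 14.1% on 17, against 6.19 to 13% on the others. Windows of 20 tested genes on chromosomes 5 and 14 held 13 and 12 called genes against at most 11 in 1000 random sets, but without predicted models no window held over 8, so near-identical copies stay open for these. A lower share of spermatids also stays open, since 53 markers of 6 other testis cell types had a pooled median of 0.18 (one-sided permutation p = 0.00061) and their list medians did not spread more than by chance (range 0.397, permutation p = 0.422), and so does loss of PCIF1 itself, which was not tested apart from these.

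WT footprint replicate 2 lay closer to the KO footprints than to the other WT footprints. A KO sample under a WT label stays open, since of 26 genes called in brain inputs and tested in footprints 15 lay nearer to WT replicates 1 and 3 in it and 11 nearer to KO (exact binomial p = 0.557, two-sided). Of 6 of these listed under 1 in WT replicates 1 and 3 and at 10 or more in all KO footprints, 5 were listed at 0 in it, among them Eno1b, which goes against a KO sample, but a 0 here may be a failed estimate. That WT replicates 1 and 3 were made apart stays open too, since the 1217 genes limma called between this pair and the other 4, against at most 3 for the other 14 pairs, restate the pattern, and the share of protein-coding signal did not part them (22.4 and 25.6% against 23.9 to 30%). The transcript AY036118, singled out after its values were seen, did part them, at 6043000 and 2814000 in this pair and listed at 0 in the other 4, but 1 transcript decides neither explanation, the labels name no batch, and no biological explanation was tested.

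Other splits of the same libraries were counted for each comparison. Those of 3 libraries against 3 have 10 splits, too few for a share under 0.05, and in each the real split was the only 1 with as many calls. The real count and the highest other were 39 and 4 for brain input RNA, 32 and 5 for footprints, 8977 and 2 for footprint against input within WT, 1052 and 1 for testes input RNA, 3732 and 0 for enrichment within HET, and 5637 and 0 for enrichment within KO. For translational efficiency 3 of 100 splits gave as many as the real 31, with a highest other of 35. These splits regroup footprints and inputs separately, although both came from the same lysates, and the 6 mice allow 10 splits, too few for a share under 0.05. Both other splits set WT footprint replicates 1 and 3 together with KO replicate 2. The rest of the splits with this footprint grouping called 9 to 16 genes, so the grouping alone does not give as many. For the loss of enrichment 8 of 100 splits gave as many as the real 1235, with a highest other of 2346, so chance is not excluded by this count. Of those 8, the 7 others keep HET and KO IP libraries apart and regroup inputs alone, which points to the structure of the IP libraries, and the 91 splits that mix the IP genotypes called 0 genes with limma.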
